A study of Canis lupus familiaris with 45 samples.

How the data were processed

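Left ventricular gene expression was measured on single-colour oligonucleotide arrays in 15 male, age-matched dogs. The dogs formed 5 groups of 3: unpaced dogs, called Day-0, and dogs in which the right ventricle was paced rapidly. The groups Day-3, Week-1 and Week-2 carry the length of pacing in their names, and the End-stage dogs were paced for 3 to 4 weeks. RNA was isolated 3 times from the tissue of each dog and each isolation was hybridised to its own array, which gave 45 arrays. Groups, dog numbers and isolation numbers were taken from the deposited labels.

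Per the submitters' processing notes, the signals were computed with GCOS 1.4 and MAS5. The deposited values are linear MAS5 signal intensity per probe set; they were not log transformed, and the authors scaled each array. The scale was checked on the values: with the lowest and highest 2% of probe sets removed, the mean was between 150.02 and 150.026 on every array. The table held 23913 probe sets, of which 77 control probe sets were left out. A sequencing depth does not apply to arrays, and the number of dogs limits the precision. Probe sets were named from the array's 2016 annotation, and symbols and positions were taken from the RefSeq gene table of the dog assembly UU_Cfam_GSD_1.0. Of the probe sets tested, 7674 carried exactly 1 gene symbol and 6528 carried none.

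Signals were log2 transformed and averaged over the 3 arrays of a dog, so that the dog was the replicate. The 40% of probe sets with the lowest mean log2 signal, those below a signal of 22.8, were left out, and 14302 were tested. One linear model with a mean per group was fitted to all 15 dogs with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). Two-sided p values were adjusted by the Benjamini-Hochberg method over the probe sets of a comparison, with a threshold of 0.05. The 4 paced groups were each compared with Day-0, consecutive paced groups were compared with each other, and a moderated F test asked for any difference among the 5 groups. Before the data were examined, the groups, these comparisons and tests, the gene lists, the rule for named genes and all but the added settings below were fixed.

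Gene lists were tested on 5278 genes, each represented by its brightest probe set. Of 42 lists written from textbook knowledge of the heart and of cell types, 36 had at least 3 measured genes and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Adjustment was over the 36 lists of a comparison. For each list the number of members past the threshold was counted over all probe sets tested and adjusted over the list alone. In every list called by camera, the median, the mean and the test had the same sign. Other splits of the dogs, counted under Other observations, also gave camera calls at the preset correlation. Camera p values at that setting therefore do not by themselves show a difference beyond the spread between dogs.

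Genes were named by a rule. For each comparison with Day-0 it took up to 8 rises and 8 falls with the largest change among probe sets past the threshold that carried 1 symbol and whose 3 paced dogs lay outside the range of the Day-0 dogs; for consecutive groups it took up to 5 of each. It also took 24 heart failure genes whatever their result, and up to 4 members of each list with the smallest p. Other named members, and probe sets without a symbol, were chosen after their values were seen.

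A contrast of the mean of the 4 paced groups with Day-0, an exact permutation test of list scores per dog (the mean log2 signal of a list minus that of all tested genes) and fits without 2 dogs whose arrays matched each other were added after the data had been examined. The permutation test ran over all 455 splits of 15 dogs into 12 and 3, so its smallest two-sided p is 0.0022. Exact permutation tests of 3 dogs against 3 cannot give a two-sided p below 0.1.

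To ask whether the 3 arrays of a dog belonged together, 200 probe sets were chosen for each dog number as those that best told apart dogs of the other numbers, and arrays of dogs sharing that number were correlated over them. Array quality was checked from the 3-prime over 5-prime signal ratios of the GAPDH and actin control probe sets, the median signal and the correlation between arrays of a dog. Whether dogs sharing a number deviated together was checked by the Pearson r of their deviations from the group means over probe sets. All 3 pairs lay above 0.1 between Day-3 and Week-1 (0.167, 0.296 and 0.318) and between Week-2 and End-stage (0.23, 0.242 and 0.102). The numbers were therefore taken to pair the dogs in these 2 comparisons. This pairing comes from the data, and the labels give no shared litter, batch or day. An effect of number in the other comparisons was not excluded by this rule. Variance between isolations and between dogs was estimated per probe set from the nested design.

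The analysis was tested on simulated data with 200 of 14302 probe sets changed and the spread of these dogs. Of the 2-fold changes 56% to 73% were recovered over the 7 comparisons, and of the 4-fold changes 93% to 98%. Between 1.92% and 5.11% of the simulated calls were false. The simulated probe sets varied independently, with no effect of dog number and no mixed arrays. These rates therefore need not hold for the real dogs.

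The alternatives were an offset before the log, quantile normalisation, median centring, other filters, no intensity trend, all 45 arrays with the dog as a random block (statmod 1.5.0), the dog number as a block, leaving out each dog or isolation number, fits of the compared dogs alone, and the mean of a gene's probe sets for the lists.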

Results

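Expression in the left ventricle was followed in dogs during the development of heart failure under rapid pacing at 240 beats per minute. Unpaced dogs (Day-0) were compared with dogs paced for 3 days, 1 week, 2 weeks or 3 to 4 weeks, the last group at end-stage heart failure. Each group had 3 dogs and each dog 3 arrays, 1 per RNA isolation, so that 45 arrays described 15 dogs. The median signal per array ranged from 33.3 to 48.6. The typical SD between RNA isolations of a dog was 0.31 on the log2 scale and the SD between dogs of a group was 0.17. The resulting typical SE of a difference between groups of 3 dogs was 0.22. The GAPDH 3-prime over 5-prime ratio, a sign of RNA quality, averaged 0.965 in Day-0 and between 0.932 and 0.956 in the paced groups. Exact two-sided permutation p values of this ratio against Day-0 were 0.3 to 0.7, where 3 dogs against 3 can reach 0.1.

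Arrays of Week-1 dog 1 and End-stage dog 1 did not group by dog. Over 200 probe sets chosen on dogs with other numbers, arrays of the same dog correlated at a Pearson r of at least 0.43 in the other 13 dogs (median 0.86), while arrays of different dogs of the same number reached at most 0.22. Arrays of these 2 dogs reached at most 0.29 with other dogs numbered 1, and dogs of different numbers were not correlated this way. These correlations are across probe sets, which are not independent replicates. Isolation 3 of Week-1 dog 1 correlated with isolations 2 and 3 of End-stage dog 1 at 0.93 and 0.94, and isolation 1 did so at 0.76 and 0.75. Isolation 2 of Week-1 dog 1 instead correlated with isolation 1 of End-stage dog 1 at 0.77. By their closest match, 4 of these 6 arrays lay with the other dog, against 0 of the other 39 arrays, each matched among dogs of its own number. Over all tested probe sets 38 of 45 arrays were closest to an array of their own dog. All arrays were kept under their labels, and counts without these 2 dogs are given for the comparisons that use them.

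**Figure D1:**
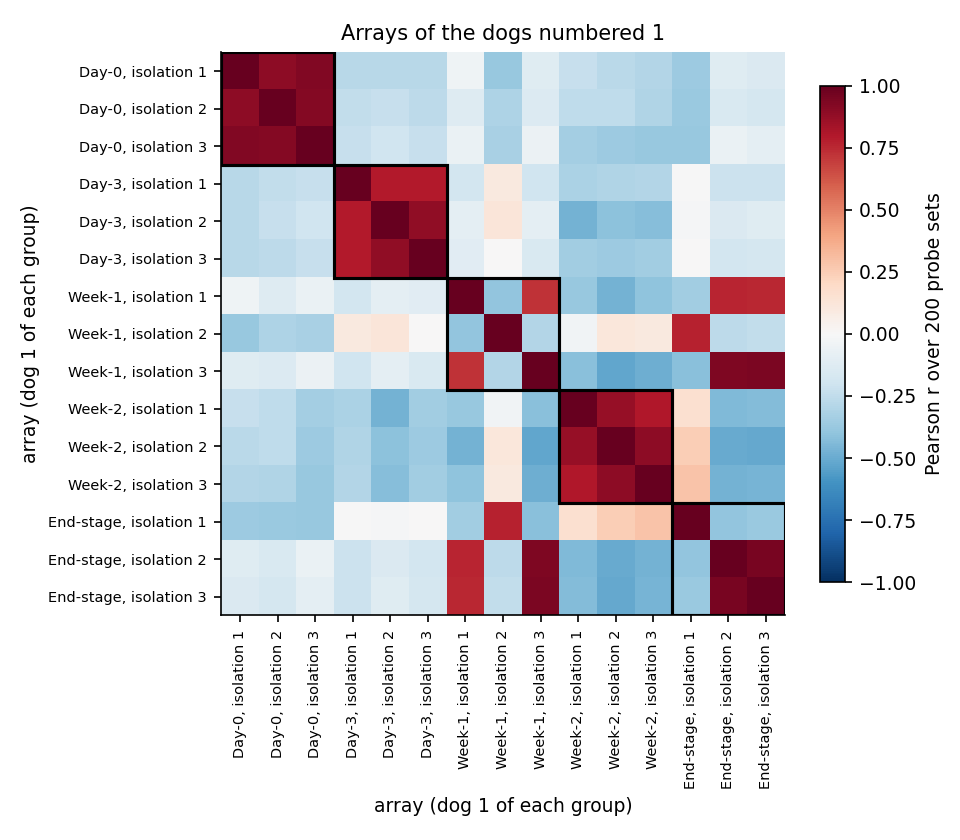
Pearson r over 200 probe sets between the 15 arrays of the dogs numbered 1, with arrays on both axes, colour for r and black outlines around arrays labelled as the same dog. Arrays of Week-1 dog 1 match End-stage dog 1 at r up to 0.94, and Week-1 isolation 2 matches End-stage isolation 1 at 0.77.

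The comparison of Day-3 with Day-0 asked what differed early in pacing. Genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, which oxidise acetyl units in mitochondria, lay lower by a median of -0.28 on the log2 scale in the Day-3 dogs. IDH3A, a subunit of mitochondrial isocitrate dehydrogenase, was 1.63-fold lower (log2 -0.71, SE 0.13, n = 3 dogs per group), IDH3B 1.36-fold lower and PDHB 1.27-fold lower. Fatty acid oxidation genes had a median of -0.20, with ACSL1 1.63-fold lower (log2 -0.70, SE 0.16), ETFDH 1.54-fold lower, MLYCD lower by a log2 value of -0.58 and ACAT1 1.48-fold lower. The fatty acid oxidation score lay below all Day-0 dogs in 2 of 3 Day-3 dogs and above them in 1 (exact permutation p = 0.4). Oxidative phosphorylation genes had a median of -0.23, with NDUFB5, NDUFS3, CYC1 and NDUFV2 between 1.31-fold and 1.39-fold lower. Fibrillar collagen and matrix genes lay higher by a median of 0.42, among them LOXL2, a collagen cross-linking enzyme, 1.64-fold higher (log2 0.71, SE 0.17).

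Camera at the preset correlation called these lists at Day-3. The adjusted p values were 4.99e-06 for the tricarboxylic acid cycle, 0.000396 for fatty acid oxidation, 4.76e-13 for oxidative phosphorylation and 4.97e-07 for matrix. The same 4 lists had adjusted p = 0.291, 0.287, 0.58 and 0.573 with an estimated correlation. With the real split included, 4 of 10 splits of the Day-3 and Day-0 dogs gave as many camera calls as the real 8. The highest count in another split was 11. The preset-correlation p values therefore do not show that these lists differed by more than dogs vary. Over all probe sets 0 members of these 4 lists passed the threshold. Adjusted over the list alone, 3 of 24 tricarboxylic acid cycle genes fell (IDH3A, IDH3B and PDHB), as did 6 of 35 fatty acid oxidation genes and 0 of 54 oxidative phosphorylation genes, and 1 of 31 matrix genes rose (LOXL2).

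Camera also called 4 lists higher at Day-3. Costamere and cytoskeleton genes had a median of 0.09 (adjusted p = 0.00236, and adjusted p = 0.287 with an estimated correlation), with TUBB2A 1.44-fold and TUBB6 1.54-fold higher. Unfolded protein and heat shock genes had a median of 0.12 (adjusted p = 0.018, and adjusted p = 0.715 with an estimated correlation). PDIA4, a protein folding enzyme of the endoplasmic reticulum, was 1.66-fold higher (SE 0.16 on the log2 scale) and was the 1 of 29 members to pass when adjusted over the list alone; the list's call stayed in 3 of 6 fits without 1 dog. Complement and coagulation genes had a median of 0.24 (adjusted p = 0.0428, and adjusted p = 0.68 with an estimated correlation), with the complement regulator CFI 2.08-fold higher; the call stayed in 2 of 6 fits without 1 dog. Macrophage markers had a median of 0.36 (adjusted p = 0.018, and adjusted p = 0.707 with an estimated correlation), with C1QC at 0.69 (SE 0.31) and TYROBP at 0.43 (SE 0.18), and this call stayed in 3 of 6 such fits.

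At Day-3, 0 single probe sets passed the threshold in limma, whose smallest adjusted p was 0.145, and 1154 had an unadjusted p under 0.05, where chance gives 715. The 3 Day-3 dogs did not overlap the 3 Day-0 dogs at 12.6% of the probe sets, where chance gives 10%. Here and below such chance values are averages. Probe sets vary together, so a single split of the dogs can lie away from them, and these shares were not computed for other splits. The count was 23 without Day-3 dog 1, 2 without Day-3 dog 2, 1 without Day-0 dog 2 or without isolation 2 of each dog, and 273 in the fit of all 45 arrays with the dog as a random block.

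At Week-1, SLC22A3, an organic cation transporter of the cell membrane, was 1.83-fold higher than at Day-0 (log2 0.87, SE 0.13, n = 3 dogs per group, limma adjusted p = 0.0404). Its log2 signal was 11.06 ± 0.12 (SD) at Week-1 and 10.19 ± 0.20 at Day-0; the gene lies on chromosome 1 at 49962647 to 50051070. Costamere, cytoskeleton and intercalated disc genes lay higher by a median of 0.10. The integrin subunit ITGB5 was 1.81-fold higher (log2 0.86, SE 0.14), the nuclear lamin LMNA 1.71-fold (log2 0.78, SE 0.15), and the tubulins TUBB and TUBB6 1.79-fold and 1.83-fold. Endothelial markers lay lower by a median of -0.27, with 7 of 7 estimates below 0, among them TIE1 at -0.40 (SE 0.15) and AQP1 at -0.33 (SE 0.13).

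Of the 35 costamere and cytoskeleton genes 0 passed over all probe sets and 7 rose when adjusted over the list alone; the camera adjusted p was 0.000741, with adjusted p = 0.357 with an estimated correlation. Matrix genes had a median of 0.41 (adjusted p = 2.39e-06, and adjusted p = 0.456 with an estimated correlation), and 2 of 31 rose when adjusted over the list alone: THBS1, a matricellular protein, 1.96-fold and LOXL2 1.56-fold. Unfolded protein and heat shock genes had a median of 0.13 (adjusted p = 0.00136, and adjusted p = 0.525 with an estimated correlation). PDIA6, CALR, SDF2L1 and PDIA4, which act in protein folding in the endoplasmic reticulum, were 1.45-fold, 1.79-fold, 3.16-fold and 1.46-fold higher, and 6 of 29 members rose when adjusted over the list alone. Oxidative phosphorylation and tricarboxylic acid cycle genes had medians of -0.26 and -0.18 (adjusted p = 5.89e-12 and 0.000549, and adjusted p = 0.475 and 0.456 with an estimated correlation). Adjusted over the list alone, 0 of 54 and 3 of 24 members fell, the latter being PDHB, IDH3A and SUCLA2. Endothelial markers (adjusted p = 0.0039) and fibroblast markers (median 0.44, adjusted p = 0.0316) had adjusted p = 0.425 and 0.518 with an estimated correlation, and 0 members of either passed when adjusted over the list alone. The fibroblast call stayed in 3 of 6 fits without 1 dog.

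At Week-1, 3 probe sets rose and 1 fell in limma, where 1287 had an unadjusted p under 0.05. Besides SLC22A3 these were probe sets without a gene symbol: 1590146_at rose 4.35-fold, 1606168_at rose 1.68-fold and 1595083_at fell 1.74-fold. The dogs of the groups did not overlap at 16.1% of probe sets, where chance gives 10%. The count was 0 without any 1 of the 6 dogs, without both dogs whose arrays matched, and without isolation 1 or isolation 2 of each dog. It was between 7 and 13 under other scalings and filters and with the 6 compared dogs alone, 0 without the intensity trend, and 377 in the fit of all 45 arrays. With the dog number as a block the count at Week-1 was higher than in the main fit, as given in the section on processing.

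After 2 weeks of pacing, 4 named genes rose and 2 fell. CLGN, a chaperone of the endoplasmic reticulum, was 4.31-fold higher than at Day-0 (log2 2.11, SE 0.27, n = 3 dogs per group, limma adjusted p = 0.0101). THBS1 was 3.43-fold higher (log2 1.78, SE 0.23, adjusted p = 0.0101), CCL2, a chemokine that attracts monocytes, 3.04-fold higher (log2 1.60, SE 0.23, adjusted p = 0.0177), and SLC22A3 1.84-fold higher (log2 0.88, SE 0.13, adjusted p = 0.0228). TIMM8A, part of the protein import machinery of mitochondria, fell 1.72-fold (log2 -0.78, SE 0.13, adjusted p = 0.041), and PPM1J, a protein phosphatase, fell 1.80-fold (log2 -0.85, SE 0.15, adjusted p = 0.049). Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, lay higher by a median of 1.23, with IER2 3.39-fold (log2 1.76, SE 0.42), JUNB 2.51-fold and DUSP1 2.13-fold higher.

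On assembly UU_Cfam_GSD_1.0, CLGN lies on chromosome 19 at 3133450 to 3164709, THBS1 on chromosome 30 at 7055241 to 7071904 and CCL2 on chromosome 9 at 38976777 to 38978526. TIMM8A lies on chromosome X at 75674818 to 75677669 and PPM1J on chromosome 17 at 63584435 to 63589674. Mean log2 signals were 10.20 ± 0.07 (SD) at Week-2 and 8.42 ± 0.33 at Day-0 for THBS1, 7.62 ± 0.06 and 6.02 ± 0.22 for CCL2, and 7.64 ± 0.29 and 5.54 ± 0.28 for CLGN.

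**Figure D2:**
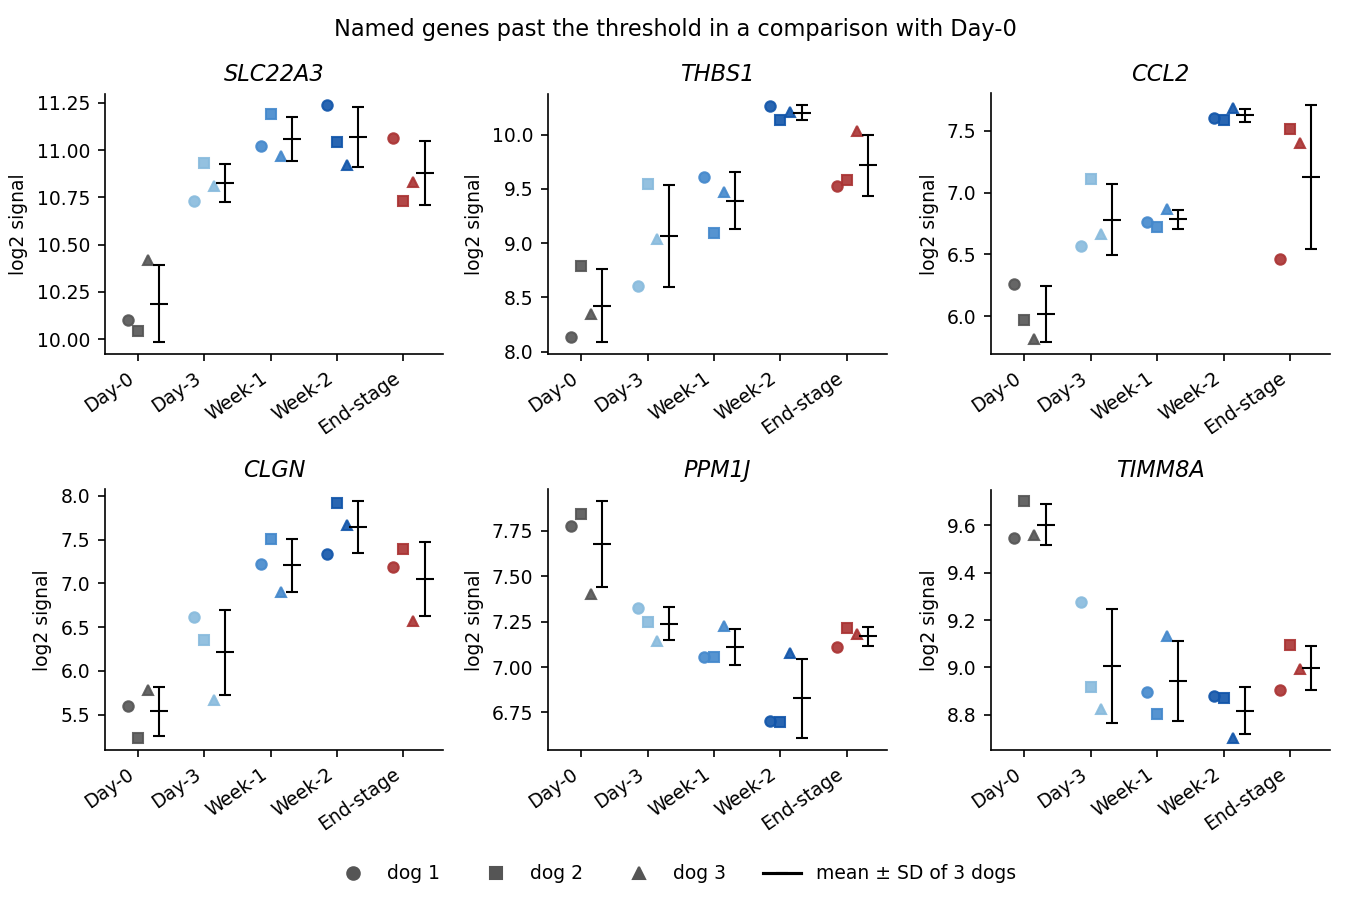
Log2 signal of 6 genes past the threshold at Week-1 or Week-2, with a point per dog (mean of its 3 arrays) and the mean ± SD of 3 dogs beside each group on the x axis. At Week-2 THBS1 averages 10.20 against 8.42 at Day-0, and TIMM8A averages 8.82 against 9.60.

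In the Week-2 lists, 5 of 9 immediate early genes rose when adjusted over the list alone and 0 over all probe sets (camera adjusted p = 2.91e-06, and adjusted p = 0.275 with an estimated correlation). Their scores per dog were 1.84, 0.38 and 1.95 above the Day-0 mean, so that 2 of 3 dogs lay above all Day-0 dogs. Matrix genes had a median of 0.40 (adjusted p = 9.09e-08, and adjusted p = 0.294 with an estimated correlation). THBS1 passed over all probe sets and 6 of 31 rose when adjusted over the list alone, among them CCN2 4.94-fold, CILP 2.67-fold and LOXL2 1.68-fold. Inflammatory genes had a median of 0.17 (adjusted p = 0.0318, and adjusted p = 0.294 with an estimated correlation), and CCL2 was the 1 of 14 to rise over all probe sets and over the list alone. The inflammatory call stayed in 3 of 6 fits without 1 dog.

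Costamere and cytoskeleton genes had a median of 0.12 at Week-2 (adjusted p = 0.00118, and adjusted p = 0.275 with an estimated correlation), and 6 of 35 rose when adjusted over the list alone, among them ITGB5 1.55-fold and TUBB6 1.95-fold. Unfolded protein and heat shock genes had a median of 0.13 (adjusted p = 0.000939, and adjusted p = 0.516 with an estimated correlation), and 3 of 29 rose over the list alone: PDIA6 by a log2 value of 0.58, XBP1 1.58-fold and PDIA4 1.46-fold. The unfolded protein call stayed in 5 of 6 fits without 1 dog, where the median lay between 0.02 and 0.27. Oxidative phosphorylation genes had a median of -0.23 (adjusted p = 4.48e-11, and adjusted p = 0.466 with an estimated correlation), and 1 of 54 fell over the list alone, NDUFS4 by 1.38-fold. Tricarboxylic acid cycle genes had a median of -0.21 (adjusted p = 0.000367, and adjusted p = 0.294 with an estimated correlation), and 1 of 24 fell over the list alone, PDHB by 1.34-fold.

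At Week-2, 6 probe sets rose and 6 fell in limma, where 1597 had an unadjusted p under 0.05. The other 6 carried no gene symbol: 1590146_at rose 3.42-fold and 1605821_at 2.40-fold, while 1584530_at, 1587628_at, 1593822_at and 1595083_at fell 2.19-fold, 2.85-fold, 2.36-fold and 1.78-fold. The dogs of the groups did not overlap at 17.3% of probe sets, where chance gives 10%. The count was 0 without Week-2 dog 2, 2 without dog 1 and 20 without dog 3. It was 4 to 6 without 1 Day-0 dog, 6 without isolation 1 and 19 without isolation 2 of each dog. It was 24 after quantile normalisation, 6 after median centring, 2 without the intensity trend, 40 with the 6 compared dogs alone and 483 in the fit of all 45 arrays. With the dog number as a block the count at Week-2 was higher than in the main fit, as given in the section on processing.

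At End-stage, matrix genes lay higher than at Day-0 by a median of 0.35. THBS1 was 2.45-fold higher (log2 1.29, SE 0.23, n = 3 dogs per group), LOXL2 1.78-fold (log2 0.83, SE 0.17), CILP, a matrix protein of connective tissue, 2.58-fold (log2 1.36, SE 0.34), and CCN2, a growth factor associated with fibrosis, 3.45-fold (log2 1.79, SE 0.51). Smooth muscle and pericyte markers lay lower by a median of -0.34, with SMTN 1.53-fold (log2 -0.61, SE 0.13) and KCNJ8 1.64-fold lower. Tricarboxylic acid cycle genes had a median of -0.26, with PDHB 1.32-fold lower (log2 -0.40, SE 0.10). Costamere and cytoskeleton genes had a median of 0.15, with LMNA 1.52-fold and TUBB6 1.71-fold higher.

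Over all probe sets 0 members of these End-stage lists passed. Adjusted over the list alone, 5 of 31 matrix genes rose (camera adjusted p = 1.38e-08, and adjusted p = 0.382 with an estimated correlation), and 2 of 8 smooth muscle and pericyte markers fell (adjusted p = 0.00443, and adjusted p = 0.382 with an estimated correlation). Of the 24 tricarboxylic acid cycle genes 1 fell (adjusted p = 9.58e-05, and adjusted p = 0.382 with an estimated correlation), and 3 of 35 costamere and cytoskeleton genes rose (adjusted p = 0.000122, and adjusted p = 0.204 with an estimated correlation). Unfolded protein and heat shock genes had a median of 0.07 (adjusted p = 0.00841, and adjusted p = 0.583 with an estimated correlation), and 5 of 29 rose over the list alone, among them CALR 1.88-fold and PDIA4 1.52-fold. The unfolded protein call stayed in 5 of 6 fits without 1 dog, where the median lay between 9.1e-05 and 0.20. Oxidative phosphorylation genes had a median of -0.22 (adjusted p = 2.14e-11, and adjusted p = 0.511 with an estimated correlation), and 0 of 54 passed over the list alone. Basement membrane genes (median 0.36, adjusted p = 0.0323) and insulin and growth factor signalling genes (median 0.17, adjusted p = 0.0405) had adjusted p = 0.511 and 0.298 with an estimated correlation, and their calls stayed in 3 and 2 of 6 fits without 1 dog. In these 2 lists 0 members passed over the list alone, with LAMA4 at 0.42 (SE 0.17), COL4A2 at 0.43 (SE 0.19) and MTOR at 0.61 (SE 0.21).

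At End-stage, 0 probe sets rose and 2 fell in limma, 1593822_at by 2.65-fold and 1595083_at by 1.77-fold, neither with a gene symbol. An unadjusted p under 0.05 was found for 1177 probe sets, and the dogs did not overlap at 14.3%, where chance gives 10%. Without End-stage dog 1, whose arrays matched those of Week-1 dog 1, the count was 6, and without both of these dogs it was 11, of which 9 rose and 2 fell. It was 0 without any other 1 of the dogs, 0 without isolation 1, 4 without isolation 2 and 5 without isolation 3 of each dog, and 0 under both other scalings, without the filter and without the intensity trend. It was 6 with the compared dogs alone and 322 in the fit of all 45 arrays. With the dog number as a block the count at End-stage was 0.

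The contrast of all 12 paced dogs with the 3 Day-0 dogs was chosen after the single comparisons had been seen. It holds the 2 dogs whose arrays matched on the same side. In this contrast SLC22A3 was 1.70-fold higher (log2 0.77, SE 0.11, adjusted p = 0.0126), CLGN 2.81-fold, THBS1 2.25-fold and CCL2 2.09-fold. TRIB1, a pseudokinase, was 2.65-fold higher (log2 1.41, SE 0.24), the cytidine deaminase family member APOBEC2 1.62-fold, the anchoring protein AKAP13 1.60-fold, LOXL2 1.66-fold, LGR4 1.73-fold, ANTXR2 1.54-fold, and the calmodulin gene CALM3 lay at a log2 value of 0.58 (SE 0.11). TIMM8A was 1.58-fold lower, the mitochondrial ribosomal protein gene MRPL38 1.48-fold, the ATP synthase assembly factor gene FMC1 1.61-fold, DHRS11 1.93-fold, PCMTD2 1.63-fold, PYROXD1 1.52-fold and ATP6V1G2 1.52-fold lower, and PPM1J lay at a log2 value of -0.59. ACTA1, which encodes skeletal alpha-actin, was 2.99-fold lower by 1 probe set (log2 -1.58, SE 0.29, adjusted p = 0.044).

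In the contrast of all paced dogs with Day-0, 20 probe sets rose and 23 fell in limma, where 1672 had an unadjusted p under 0.05. All 12 paced dogs lay outside the range of the 3 Day-0 dogs at 2.52% of probe sets, where chance gives 0.44%. The count was 28 without both dogs whose arrays matched. It was 1 without Day-0 dog 2 or Day-0 dog 3, 5 without Day-0 dog 1, 111 without Day-3 dog 1, and between 9 and 30 without any other 1 of the dogs. It was 26 without isolation 1 and 13 without isolation 3 of each dog, 68 after quantile normalisation, 21 without the filter and 81 with a stricter one, 6 without the intensity trend and 701 in the fit of all 45 arrays. With the dog number as a block the count for all paced dogs was higher than in the main fit, as given in the section on processing.

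Scores per dog separated 4 lists between the paced and the unpaced dogs. The matrix score was higher by 0.50 (SD of paced dogs 0.21), the costamere and cytoskeleton score by 0.20 (SD 0.07) and the insulin and growth factor signalling score by 0.16 (SD 0.08), and the tricarboxylic acid cycle score was lower, at -0.24 (SD 0.09). In each of the 4 lists 12 of 12 paced dogs lay outside the range of the Day-0 dogs. Camera did not call the insulin and growth factor signalling list in this contrast. Each exact permutation p was 0.0022, the smallest that 455 splits can give, and 0.0198 after adjustment over 36 lists. This test was chosen after results had been seen. Its splits treat all dogs as exchangeable, although dogs of a number deviated together and arrays of Week-1 dog 1 and End-stage dog 1 matched. The test was not repeated within numbers or without these dogs, so its p values may be too small. The inflammatory score lay above all Day-0 dogs in 11 of 12 paced dogs (0.21, permutation p = 0.0132, adjusted 0.095). The oxidative phosphorylation score lay below all Day-0 dogs in 7 of 12 (-0.23, permutation p = 0.0176, adjusted 0.105), and the unfolded protein score lay above them in 8 of 12 (0.22, permutation p = 0.0264, adjusted 0.136). Fibroblast markers, 6 of whose 9 measured genes are also in the matrix list, lay above all Day-0 dogs in 6 of 12 paced dogs (0.37, permutation p = 0.0484, adjusted 0.218). The fatty acid oxidation score lay below all Day-0 dogs in 7 of 12 paced dogs and above them in 1 (-0.10, permutation p = 0.198, adjusted 0.404). The complement and coagulation score lay above them in 7 of 12 and below in 2 (0.16, permutation p = 0.185, adjusted 0.404).

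**Figure D3:**
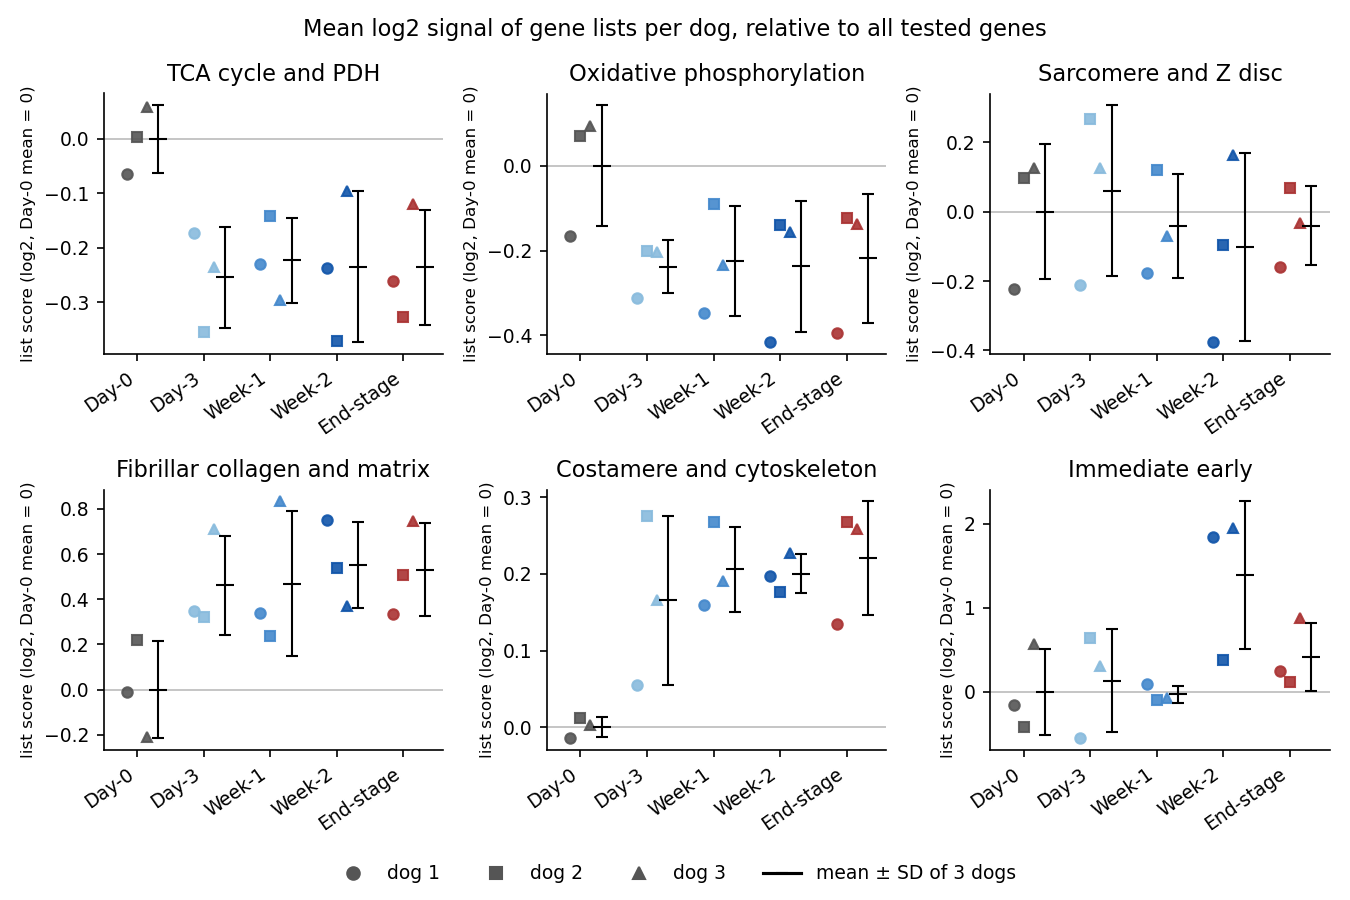
List score of 6 gene lists (mean log2 signal of the list minus that of all tested genes, Day-0 mean set to 0), with a point per dog and the mean ± SD of 3 dogs beside each group on the x axis. The tricarboxylic acid cycle (TCA) and pyruvate dehydrogenase (PDH) score averages between -0.25 and -0.22 in the paced groups, and the matrix score between 0.46 and 0.55.

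By camera 8 of 36 lists were called for all paced dogs and by fry 3, while 0 were called with an estimated correlation. In each of the 7 other comparisons fry called 0 lists, and camera with an estimated correlation also called 0. Among 54 oxidative phosphorylation genes 15 fell when adjusted over the list alone (median -0.22, camera adjusted p = 5.86e-15, and adjusted p = 0.383 with an estimated correlation), with NDUFV2 1.41-fold and NDUFS4 1.30-fold lower. Among 35 fatty acid oxidation genes 5 fell over the list alone (median -0.20, adjusted p = 0.0238, and adjusted p = 0.383 with an estimated correlation), with CD36, a fatty acid transporter, 1.48-fold and HADHA 1.41-fold lower. Over the list alone 4 of 24 tricarboxylic acid cycle genes fell, and 5 of 31 matrix genes, 8 of 35 costamere and cytoskeleton genes and 8 of 29 unfolded protein genes rose. Their camera adjusted p values were 9.97e-06, 1.98e-09, 0.000105 and 0.00111, with adjusted p = 0.323, 0.323, 0.195 and 0.457 with an estimated correlation. Fibroblast markers (median 0.36) and complement and coagulation genes (median 0.25) had camera adjusted p values of 0.0368 and 0.0419, and both had adjusted p = 0.457 with an estimated correlation.

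Of 24 heart failure genes fixed in advance, 17 had a probe set among those tested. In the main fit 0 of these 17 passed the threshold in any of the 4 comparisons with Day-0. COL1A1 lay between 0.96 and 1.10 (SE 0.53) above Day-0 in each paced group, FN1 between 0.56 and 0.80 (SE 0.38), and TIMP1, an inhibitor of matrix proteases, between 0.43 and 0.73 (SE 0.21). COL3A1 lay between 0.20 and 0.51 (SE 0.49), and MMP2 lay below Day-0, between -0.61 and -0.07 (SE 0.40). RYR2, the calcium release channel of the sarcoplasmic reticulum, lay below the Day-0 mean in 12 of 12 paced dogs and at -0.67 (SE 0.14, limma adjusted p = 0.0796) at Week-2. With the dog number as a block RYR2 passed at Week-2 (limma adjusted p = 0.0392). ATP2A2, the calcium pump of the sarcoplasmic reticulum, lay between -0.19 and -0.15 (SE 0.20) by its brightest probe set, while another bright one lay between -0.57 and -0.35 (SE 0.19). HADHA lay between -0.57 and -0.41 (SE 0.16), and its other probe set between -0.28 and -0.18 (SE 0.15). MYH7 lay between -0.15 and -0.10 (SE 0.23) and the gap junction gene GJA1 between -0.87 and -0.47 (SE 0.44). ANKRD1 lay between -0.63 and -0.08 (SE 0.29), SLC8A1 between -0.56 and -0.33 (SE 0.41) and PDK4 between 0.07 and 0.64 (SE 0.51). KCND3 lay between -0.19 and 0.17 (SE 0.36), KCNIP2 between -0.42 and 0.20 (SE 0.56) and KCNJ2 between 0.0006 and 0.32 (SE 0.39). ACTA1 on chromosome 4 lay at -2.26 (SE 0.36, limma adjusted p = 0.145) at Day-3 by its brightest probe set, 1605145_at. Its 3 other probe sets lay between -0.33 and 0.07 at Day-3 and none of them passed in a comparison with Day-0, so its probe sets disagree. NPPA, NPPB, MYH6, PLN, CPT1B and CKM had no probe set with that symbol in the annotation used, and POSTN was among the dim probe sets left out.

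**Figure D4:**
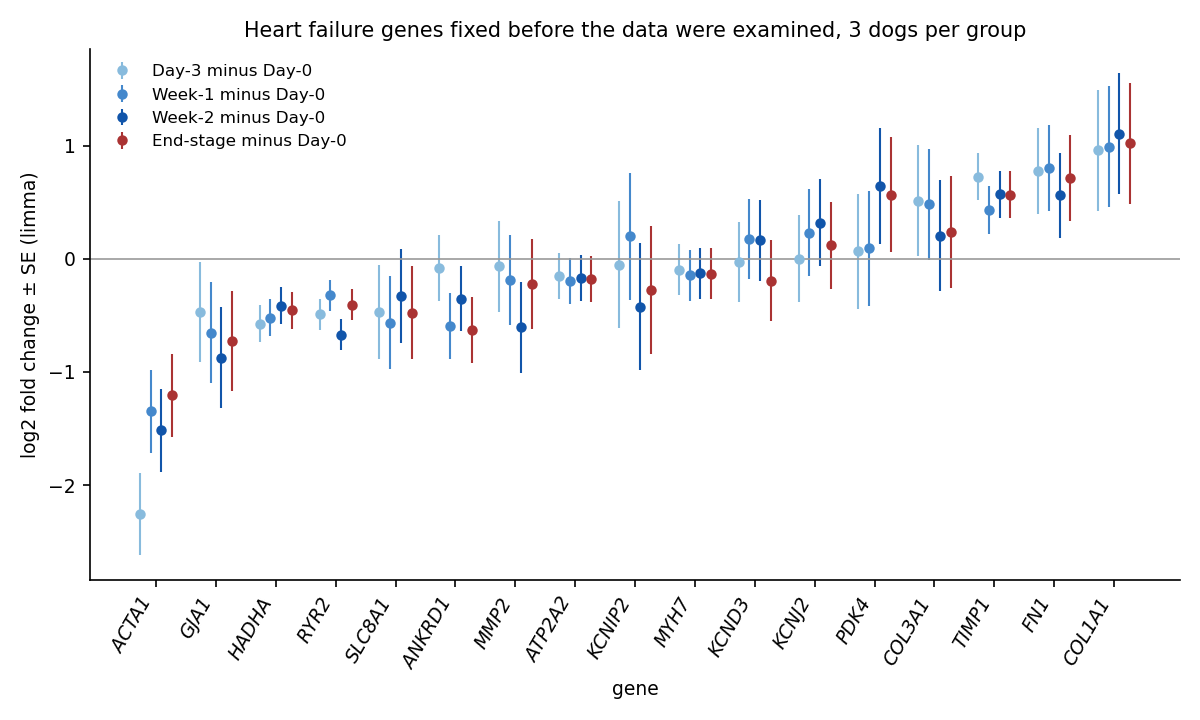
Log2 fold change ± SE (limma, 3 dogs per group) of 17 heart failure genes on the x axis, in each paced group minus Day-0. ACTA1 lies lowest, at -2.26 at Day-3 by 1 of its 4 probe sets, and COL1A1 lies highest, between 0.96 and 1.10.

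Consecutive stages were compared to ask what differed between them. Immediate early genes lay higher at Week-2 than at Week-1 by a median of 1.14, with FOS 22.1-fold (log2 4.47, SE 1.32, n = 3 dogs per group), IER2 2.47-fold, JUNB 2.21-fold and DUSP1 2.03-fold higher, and 8 of 9 rose when adjusted over the list alone (camera adjusted p = 2.68e-09, and adjusted p = 0.258 with an estimated correlation). At End-stage they lay lower than at Week-2 by a median of -0.87 (camera adjusted p = 1.64e-05, and adjusted p = 0.889 with an estimated correlation), with JUNB at -0.98 (SE 0.36) and IER2 at -1.10 (SE 0.42) and 0 of 9 past the threshold over the list alone. Endothelial markers lay higher at Week-2 than at Week-1 by a median of 0.18 (adjusted p = 0.00622, and adjusted p = 0.353 with an estimated correlation), with VWF, the von Willebrand factor, 1.65-fold higher and the 1 of 7 to rise over the list alone. The endothelial call stayed in 5 of 6 fits without 1 dog, where the median lay between 0.05 and 0.33. Interferon response and antigen presentation genes had a median of 0.31 (adjusted p = 0.00622, and adjusted p = 0.995 with an estimated correlation), with MX2 at 0.43 (SE 0.16) and PSMB8 at 0.58 (SE 0.23), and 0 of 16 passed over the list alone. Between Day-3 and Week-1 camera called 0 lists, and 3 with the dog number as a block, all lower at Week-1. These were sarcomere genes (median -0.12), ubiquitin proteasome genes (median -0.13) and endothelial markers (median -0.19), each at an adjusted p of 0.0251 and adjusted p = 0.92 with an estimated correlation.

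Single probe sets past the threshold in limma numbered 0 between Day-3 and Week-1, 0 between Week-1 and Week-2 and 0 between Week-2 and End-stage, the last being 1 with the dog number as a block. Unadjusted p values under 0.05 numbered 689, 826 and 600, where chance gives 715, and the dogs did not overlap at 9.31%, 11.2% and 9.28% of probe sets, where chance gives 10%. The moderated F test called 0 probe sets across the 5 groups, with 1054 at an unadjusted p under 0.05. In the fit of all 45 arrays these counts were 7, 30, 3 and 493, and without both dogs whose arrays matched they were 0, 0, 0 and 6.

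Changes against Day-0 at Day-3 and at End-stage shared the 3 Day-0 dogs. The probe sets called at both times numbered 0, with limma calling 0 at Day-3. The covariance of the log2 fold changes over probe sets was 0.058, against a simulated mean of 0.044, and 23 of 100 draws were as large. In each draw unchanged groups were made from deviations of dogs from their group means. There 3 dogs drawn at random from all 15, rather than the Day-0 dogs, served as the shared control. Probe sets called at both Week-1 and Week-2 numbered 3, SLC22A3 and 1590146_at higher and 1595083_at lower. Those called at both Week-2 and End-stage numbered 2, 1593822_at and 1595083_at, both lower. Against the same simulated mean of 0.044, the covariance was 0.0657 for Week-1 and Week-2, with 15 of 100 draws as large, and 0.0679 for Week-2 and End-stage, with 13 of 100. For Week-1 and End-stage, which shared 1595083_at, it was 0.0695, with 10 of 100. The 3 Day-0 dogs are too few to be divided between the comparisons.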

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

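The tests of matching arrays, of the share of heart muscle cells and of single Week-2 dogs were chosen only after their results had been seen; those of RNA degradation and of handling were not.

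Among 30 sets of 9 arrays, each a quality measure in a group, 3 held an array far from the others. For independent values chance gives about 1 in 20, or 1.5 sets. The 9 arrays come from 3 dogs and the measures are related, so this rate need not hold. The median signal of isolation 3 of Week-1 dog 2 was 46.8, with the others between 34.3 and 39.5. For isolation 1 of End-stage dog 1 it was 48.6, with the others between 33.8 and 41.0. That array also had the lowest correlation with the other arrays of its dog, 0.930 against 0.951 to 0.967. The change against Day-0 differed between consecutive groups in 4 camera calls on 3 gene lists. Between Week-2 and Week-1 the medians differed by 1.14 for immediate early genes, 0.18 for endothelial markers and 0.31 for interferon response genes, and between End-stage and Week-2 by -0.87 for immediate early genes. None of these 4 calls held with an estimated correlation.

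Arrays of Week-1 dog 1 and End-stage dog 1 matched across the 2 dogs. The highest correlation between them was 0.94, above the lowest of 0.43 within the other 13 dogs, which mixed or mislabelled arrays would give. Noise on single arrays would not draw 4 of the 6 arrays to the other dog, and related dogs would still match themselves, whereas the lowest correlation within these dogs was -0.39. The matches form sets of 4 and 2 arrays, so an exchange among these 6 arrays alone would not leave 3 per dog. Which arrays carry the right label stays open, and no biological explanation other than related dogs was tested.

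In the paced dogs tricarboxylic acid cycle genes were lower and matrix and costamere genes higher. With the GAPDH ratio of each dog in the fit, the tricarboxylic acid cycle median was -0.23, as without it (camera adjusted p = 1.66e-05, and adjusted p = 0.394 with an estimated correlation). The fold changes of all genes moved by a median of 0.03. RNA degradation as this ratio measures it therefore did not account for the tricarboxylic acid cycle median. The ratio averaged 0.965 at Day-0 and 0.932 to 0.956 in the paced groups, so this fit could hardly move a difference between them. The actin ratio was not put in the fit. A lower share of heart muscle cells would raise markers of 6 other cell types alike. Without genes of the 3 lists above, fibroblast, macrophage and adipocyte markers shifted by 0.21, 0.20 and 0.32. Smooth muscle and pericyte, endothelial, and T cell and NK cell markers shifted by -0.23, -0.12 and -0.11. Permutation p values of single types were 0.064 to 0.4. The sarcomere score shifted by -0.03 (permutation p = 0.811). Over types the shifts had an SD of 0.22, with a permutation p of 0.125 over 455 splits. These splits ask for any paced difference, not for a common rise, so this SD cannot decide the question. Before that test, the tricarboxylic acid cycle score minus the sarcomere score gave -0.21 (permutation p = 0.127), and fibroblast minus endothelial markers gave 0.48 (permutation p = 0.011), but 6 of 9 fibroblast markers belong to the matrix list. An effect of pacing and a change in cell composition were therefore not told apart, and every value rests on the same 3 Day-0 dogs.

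Immediate early genes were higher in Week-2 dogs, 1 of which lay within the Day-0 range, with an exact permutation p of 0.2 for the score and adjusted p = 0.275 with an estimated correlation. Without 1 Week-2 dog the lowest median was 0.80 and the camera call stayed. Handling that differed between RNA isolations would make isolations of a dog differ, but their pooled SD was 0.12 against a shift of 1.39. Handling shared by the 3 isolations of a dog would leave this SD small, so the test does not cover it. Handling of the heart at harvest acts on a whole dog, as pacing does, and the 2 cannot be told apart, since each group was harvested at its own time; 2 of 3 Week-2 dogs lay above all Day-0 dogs.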

How the results depend on the processing

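The fits of all paced dogs and the fits without Week-1 dog 1 and End-stage dog 1 were chosen only after the data had been seen; the other alternatives were planned. No named gene or list past its threshold turned direction in these alternatives, except that the unfolded protein median at Day-3 was -0.01 without Day-3 dog 2, where its call was lost. Of 75 results for named genes 7 were past the threshold. These 7 stayed after quantile normalisation, with the offset and in the fit of all 45 arrays, where 10 others came to pass. With the dog number as a block the 7 also stayed and 1 other came to pass, RYR2 at Week-2. After median centring 5 stayed, without the filter 5 and without the intensity trend 2, and without Week-2 dog 2 the 6 calls at Week-2 were all lost. Without Week-2 dog 1 or dog 3, 5 and 1 of these 6 were lost. Leaving out Day-0 dog 1, 2 or 3 lost 4, 5 and 3 of the 7 calls, and the call at Week-1 was lost without each Week-1 dog. Of 34 list calls, 34 stayed with the offset and 31 after quantile normalisation. Calls for the tricarboxylic acid cycle, oxidative phosphorylation, matrix and costamere lists against Day-0 stayed without each dog in turn. With 1 of the 6 dogs left out, insulin and growth factor signalling at End-stage and complement at Day-3 kept their calls in 2 of 6 fits, and in 4 and 7 of 13 other alternatives. Macrophage markers and unfolded protein genes at Day-3, fibroblast markers at Week-1, inflammatory genes at Week-2 and basement membrane genes at End-stage did so in 3 of 6, and interferon response genes between Week-1 and Week-2 in 4 of 6. Unfolded protein genes at Week-1, Week-2 and End-stage, and endothelial markers between Week-1 and Week-2, did so in 5 of 6. Where Day-0 dog 1 or dog 2 was left out, another ACTA1 probe set was the brightest and its Day-3 value lay near 0.

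Counts of probe sets moved as follows, in the order Day-3, Week-1, Week-2 and End-stage against Day-0; unless the alternative's construction shows it, the cause was not tested. In the fit of all 45 arrays they were 273, 377, 483 and 322, with 7, 30 and 3 between consecutive groups, 493 in the F test and 701 for all paced dogs. That fit gives every probe set the same correlation between arrays of a dog, 0.29. Among the brightest 4767 probe sets a median of 48% of the variance lay between dogs. Arrays there count partly as replicates, so these higher counts do not replace those over dogs. Quantile normalisation gave 13 at Week-1, 24 at Week-2, 0 at End-stage and 68 for all paced dogs, and median centring 10 at Week-1, 6 at Week-2 and 0 at End-stage. Without the filter 7, 0 and 21 were called at Week-1, at End-stage and for all paced dogs, and with 60% left out 12 at Week-1 and 81 for all paced dogs. Without the intensity trend 0, 2, 0 and 6 were called at Week-1, Week-2, End-stage and for all paced dogs. With the compared dogs alone 7, 40 and 6 were called at Week-1, Week-2 and End-stage, and 1 between Week-1 and Week-2. Without Week-1 dog 1 and End-stage dog 1, 0 were called at Week-1, 11 at End-stage, 6 in the F test and 28 for all paced dogs. List counts moved to 11 at Week-2 with the compared dogs alone. Between Day-3 and Week-1 they moved to 2 after quantile normalisation and 2 with 60% left out, and between Week-2 and End-stage to 2 without the filter and 4 without the 2 dogs.

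With the dog number as a block, the counts were 17 at Week-1, 88 at Week-2, 0 at End-stage, 1 between Week-2 and End-stage, 1 in the F test and 219 for all paced dogs, and 3 lists were called between Day-3 and Week-1. The numbers were taken to pair the dogs between Day-3 and Week-1 and between Week-2 and End-stage, where the block changed no other call. In the other comparisons not all 3 pairs lay above 0.1. Yet 607 of 14302 probe sets differed by number over all groups in the limma fit with the block, at an adjusted p under 0.05. An effect of number may therefore also act in the comparisons with Day-0, whose main fits leave it out. Of 30 pairs of dogs with the same number 17 correlated above 0.1, and 14 of 15 dogs correlated best with their own number. The mean signal of dogs numbered 1 lay between 221 and 227 and that of the others between 233 and 249, a hint from the data of a shared step by number.

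Leaving out 1 dog or 1 isolation number gave 0 to 23 probe sets at Day-3 (23 without Day-3 dog 1), 0 to 5 at Week-1, 0 to 20 at Week-2 (0 without Week-2 dog 2, 20 without dog 3), 0 to 6 at End-stage (6 without End-stage dog 1), 0 to 1 for each consecutive comparison, 0 to 13 in the F test (13 without Day-3 dog 1, 9 without Day-3 dog 2) and 1 to 111 for all paced dogs (1 without Day-0 dog 2 or 3, 111 without Day-3 dog 1). List counts ranged from 6 to 9, 6 to 8, 7 to 11 and 5 to 13 against Day-0, from 0 to 4, 1 to 5 and 1 to 4 between consecutive groups, and from 6 to 12 for all paced dogs. Dim signals limit precision: the SD between isolations was 0.57 without the filter and 0.31 with it. Without the filter the covariance of Day-3 and End-stage changes lay -0.0012 from its simulated mean, against 0.014 with it.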

Other observations

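The tests of list scores and of other splits of the dogs were chosen only after results had been seen. In the list scores, paced minus unpaced, ion channel and gap junction genes lay at -0.12, with 9 of 12 paced dogs below all Day-0 dogs (permutation p = 0.0615, adjusted 0.246), and creatine and adenine nucleotide transfer genes lay at -0.12 (adjusted 0.31). The natriuretic peptide and fetal program list, measured here without NPPA and NPPB, lay at -0.10, with 9 of 12 dogs below all Day-0 dogs (adjusted 0.417). TGF-beta signalling genes lay at 0.08, with 9 of 12 dogs above all Day-0 dogs (adjusted 0.404), and matrix proteases and inhibitors at 0.10, with 9 of 12 above (adjusted 0.459). Beta-adrenergic and cAMP signalling genes lay at 0.09, renin-angiotensin and endothelin genes at 0.08, calcium handling genes at 0.04 and apoptosis genes at 0.10. Basement membrane genes lay at 0.17, with 6 of 12 dogs above all Day-0 dogs (adjusted 0.31), and immediate early genes at 0.48, with 4 above and 1 below (adjusted 0.466). Interferon response genes lay at 0.09. Sarcomere and Z disc genes lay at -0.03, glycolysis genes at 0.01, ubiquitin proteasome genes at 0.01, autophagy and lysosome genes at 0.05, oxidative stress defence genes at 0.03, cytosolic ribosome genes at 0.01, cell cycle genes at 0.04 and hypoxia response genes at 0.03. None of the lists in this paragraph passed after adjustment.

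Among markers of other cell types, smooth muscle and pericyte markers lay at -0.19 in the paced dogs, endothelial markers at -0.12, T cell and NK cell markers at -0.11, macrophage markers at 0.20, adipocyte markers at 0.32 and atrial cardiomyocyte markers at -0.13, and none passed after adjustment. The smooth muscle and pericyte score lay below all Day-0 dogs in 3 of 3 dogs at Week-2 and 3 of 3 at End-stage (-0.23 and -0.34, exact permutation p = 0.1 for each, the smallest possible). B cell, neutrophil, mast cell and mesothelial marker lists had 1 measured gene each, and Schwann cell and red blood cell lists 2 each, so they were not tested. The actin 3-prime over 5-prime control ratio averaged 0.154 at Day-0 and between 0.185 and 0.207 in the paced groups, at exact permutation p values of 0.3 to 0.5.

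Other splits of the dogs were counted for each result. With 3 dogs against 3 there are 10 splits, the real one included. These are too few for a share under 0.05, and a real count of 0 is reached by every split by construction. For probe sets, 10 of the 10 splits called as many at Day-3 (real 0, highest other 1), 1 at Week-1 (real 4, highest other 0), 1 at Week-2 (real 12, highest other 1) and 1 at End-stage (real 2, highest other 1). Between consecutive groups it was 10 of 10 each time, with 0 in the real split and at most 0, 1 and 1 in the others. For gene lists, as many were called by 4 splits at Day-3 (real 8, highest other 11), 4 at Week-1 (real 7, highest other 8), 3 at Week-2 (real 7, highest other 8) and 3 at End-stage (real 8, highest other 9). Between consecutive groups it was 10 (real 0, highest other 12), 9 (real 3, highest other 7) and 9 (real 1, highest other 9). Between Day-3 and Week-1, where dogs of a number deviated together, the 3 other splits that part all 3 numbers called 0 to 1 lists, and the 6 splits that put both dogs of some number together called 5 to 12. Between Week-2 and End-stage these were 1 to 3 and 0 to 9 lists. For probe sets the splits that part all 3 numbers called 0 in both comparisons, as the real split did. All counts of groupings given here include the real one. Of 100 groupings of all 15 dogs, 2 called as many probe sets as the contrast of all paced dogs (real 43, highest other 71), a share under 0.05. The contrast was chosen after the single comparisons had been seen and its count was 1 without Day-0 dog 2 or dog 3, so chance is not taken as excluded for it. Chance cannot be excluded for its list count, reached by 27 of 100 (real 8, highest other 13). The F test called 0 in the real grouping, a count that 100 of 100 reach by construction (highest other 3), so chance was not tested there.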
